A study of Mus musculus with 2 samples.

How the data were processed

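The study measured single-cell RNA in regulatory T cells (Treg), the Foxp3-expressing CD4 T cells that restrain immune responses. Cells positive for eGFP driven from the Foxp3 locus were sorted from the spleens of 1 wild-type (WT) mouse and 1 mouse lacking Lta (Lta-/-), 20000 cells per genotype, per the labels' protocols. Each sort was marked with its own hashtag, an antibody to a common surface protein that carries a DNA barcode, and both were pooled into 1 droplet capture with a 3′ gene expression chemistry. The 2 libraries of the series are the mRNA library and the hashtag library of that capture. Files were given for the mRNA library, and its matrix also holds the 2 hashtag rows, so genotype was read from those rows. The hashtag library has no file of its own here.

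The deposited matrix holds whole-number counts of unique molecular identifiers (UMIs), 1 per captured molecule, with no normalization. Per the file headers the matrix was written by Cell Ranger 6.0.1, and the submitters' processing notes also name Seurat and the mouse build GRCm38; which step Seurat served is not given in the sources used here. The matrix has 32285 gene rows and 5217 barcodes, the lowest with 500 gene UMIs. In all barcodes there were 22208151 gene UMIs. Gene coordinates were taken from GENCODE M21 on GRCm38, which held 32158 of the gene IDs. Because a 3′ chemistry counts molecules near the transcript end, and the labels do not give which part of Lta was removed, Lta UMIs report on the labels only as far as the counted part is affected.

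Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, 4634 in all; 583 were left out. A hashtag was called present above the 99th percentile of a negative binomial fitted to its background cells with their top 0.5% left out, above 71 counts for WT and above 93 for Lta-/-. Barcodes with exactly 1 hashtag were used, 2104 WT and 2182 Lta-/- cells. Barcodes with both hashtags that passed the filters numbered 348 (7.51%) and were left out. Doublets within 1 genotype carry 1 hashtag and stay in. Scrublet (in scanpy 1.11.5) marked 0 cells at its automatic threshold of 0.53 and is treated as not having worked: the median score of hashtag doublets was 0.126 against 0.0893 for single-hashtag cells. The kept cells held 9807080 UMIs for WT (median 4494.5 per cell) and 9526500 for Lta-/- (median 4051.5).

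Cells were clustered with Leiden (leidenalg 0.10.2, resolution 1) on a shared-neighbour graph of 15 neighbours in 20 principal components of 2000 variable genes. All genes of the 15 gene-group lists, ribosomal protein, mitochondrial, T cell receptor and immunoglobulin segment genes were kept out of the clustering. A cluster was named from fixed marker lists when at least 3 markers of a list were 1.5-fold higher than in the other cells and seen in at least 5% of its cells. Markers that name a class are not reported as results between classes. A cluster stayed unnamed with fewer markers, or when it was shallow against the library and had no marker of its name among its 10 leading genes. The gene lists, the marker lists, the rule for named genes between genotypes and classes and most alternatives were fixed before the data were examined. The steps of cluster naming beyond the marker lists, and the alternatives on Scrublet scores, cells of another type, shallow cells, Leiden seeds, genotype genes in the clustering, the scaling of the genotype ratios, the resting-like clusters taken alone, and for genotype the cells with most UMIs, thinned shares, class composition and CPM without ribosomal protein and mitochondrial genes, and for genotype and other classes the count minimums, were set after that.

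With 1 mouse per genotype there is no test of genotype, and cells are not replicates. Classes were compared over both mice and within each, without a test over the mice, so no p-value is given. UMIs were summed per group of cells and divided by that group's total, as counts scaled to 1e+06 (CPM). The deposited counts give exact Poisson intervals for CPM, exact conditional binomial intervals for ratios and exact binomial (Clopper-Pearson) intervals for shares of cells, all at 95%. They cover counting error only, not differences between mice, and molecules of 1 cell are not independent draws. The interval of a list median was instead taken from the ordered log2 ratios of its genes. It covers the spread among those genes, not counting error or differences between mice. For lists of few genes it runs from the lowest to the highest gene and can fall short of 95%. A gene entered a comparison with at least 30 UMIs in both groups together and was called higher or lower at 1.5-fold. A sum of 0 was set to 3 counts, and the fold is then a lower bound. For each list the median log2 ratio was placed among 10000 random lists of the same size matched on expression, as a description of this library.

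Genes were named by 1 rule. For genotype and for effector-like against resting-like cells it took the 25 listed genes with the largest ratio among those with at least 100 UMIs and at least 1.5-fold apart, always Lta, Ltb, Tnf, Ltbr, Foxp3, Il2ra, Ctla4 and Il10, and the 5 highest and 5 lowest unlisted genes not used in the clustering with at least 200 UMIs. Unlisted genes that serve as markers were passed over. For other classes it took 8 listed genes, and the same was then applied to genotype within a class. Shares of cells with a UMI were also computed after thinning each cell to 2000 UMIs, which left out 134 WT and 120 Lta-/- cells.

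The steps were run on simulated data. Simulated gene counts varied by counting error only, so coverage near the set level of the intervals was built in. UMIs of the same cell are not independent draws. The gene rates below therefore do not carry over to genes with UMIs in few cells. For the genotype comparison over 10573 simulated genes, 95.6% of intervals held the true ratio; 98.5% of 67 genes made 2-fold apart and 39.4% of 66 made 1.5-fold apart were called in their direction. Of genes made equal, 14.6% of 1775 with 30 to 99 UMIs and 0.395% of 8599 with at least 100 UMIs were at least 1.5-fold apart from counting alone. Simulated hashtags gave 98.9% of 4800 single cells their own tag. Their background was drawn from a negative binomial, the form that the cutoff at the 99th percentile assumes. That share was therefore built in too and does not check the real calls. Alternatives covered cell filters, doublets, clustering, count splitting, depth, scaling and count minimums. numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used under Python 3.11.15.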

Results

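Splenic Treg were profiled from 1 WT and 1 Lta-/- mouse in 1 pooled capture, and hashtags assigned 2104 cells to WT and 2182 to Lta-/-. The totals were 9807080 and 9526500 UMIs, with medians of 4494.5 and 4051.5 UMIs per cell. There were no replicate mice, so the difference between genotypes has no replicate check and genotype cannot be separated from mouse. Intervals below cover counting error only, except those of list medians, which cover the spread among the list's genes. All coordinates are GRCm38.

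The first question was whether the labelled genotypes showed in the deleted gene. Lta (ENSMUSG00000024402, chromosome 17, 35203165 to 35205351), which encodes lymphotoxin alpha, stood at 59.0 CPM in WT cells (interval 54.3 to 64.0, 579 UMIs) and at 6.09 CPM in Lta-/- cells (interval 4.62 to 7.87, 58 UMIs). The log2 ratio of Lta-/- over WT was -3.28 (interval -3.69 to -2.89), a 9.70-fold lower level. An Lta UMI was found in 17.5% of WT cells and in 2.34% of Lta-/- cells, and after thinning in 9.04% and 0.970%. Over all cells the share was 9.78% (interval 8.90 to 10.7). The sort left no other cell type in number to give a background for these shares. The share in Lta-/- cells is not a measure of it, since transcripts still made from the targeted allele were not excluded. Tnf and Ltb lie beside Lta on chromosome 17. Tnf, a related inflammatory ligand (35199381 to 35202007), was 1.53-fold lower in Lta-/- cells (log2 -0.61, interval -0.90 to -0.32). Ltb, the partner that anchors lymphotoxin at the cell surface (35194439 to 35196320), was close in both, at 1253 CPM in Lta-/- and 1349 CPM in WT (log2 -0.11). Ltbr, the receptor for the lymphotoxin heterotrimer, had 1 UMI in Lta-/- and 0 in WT cells.

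The sort was for Foxp3-eGFP. Foxp3 UMIs (chromosome X, 7573644 to 7595245) were found in 38.1% of all cells (interval 36.6 to 39.5), in 41.1% of WT and 35.1% of Lta-/- cells, and in 22.6% and 18.7% after thinning. No cells that should lack Foxp3 were present in number, so its background was not measured. Foxp3 CPM was 142 in WT and 120 in Lta-/- (log2 -0.25, interval -0.36 to -0.13). The direction was not the same in every class of the clustering below. Foxp3 was higher in Lta-/- effector-like cells (0.34, interval 0.03 to 0.64) and lower in resting-like cells (-0.27, interval -0.53 to -0.01). In follicular-like cells it was -0.18 (interval -0.44 to 0.07). Of other T cell and Treg transcripts, Ctla4 was found in 34.3%, Il2ra in 43.1%, Cd4 in 43.6%, Ikzf2 in 76.2%, Trac in 87.2% and Cd3e in 90.5% of all cells. Il2ra, the high-affinity interleukin 2 receptor chain, was 231 CPM in WT and 180 CPM in Lta-/- (log2 -0.36, interval -0.45 to -0.27), and Ctla4, an inhibitory receptor, was 124 and 131 CPM (log2 0.08, interval -0.04 to 0.19). In effector-like cells both were higher in Lta-/-, Il2ra at 0.66 (interval 0.34 to 0.98) and Ctla4 at 0.74 (interval 0.50 to 0.98). In follicular-like and resting-like cells Il2ra was -0.26 and -0.23, and Ctla4 0.00 and 0.15. Markers of other cells ranged widely. Of the B cell markers, Ighm was found in 55.0%, Cd74 in 10.5%, Cd79b in 6.79% and Cd79a in 0.560% of all cells, and the myeloid marker Cst3 in 38.5%, examples chosen after their values were seen. Whether these came from other cells, free RNA or the Treg was not tested. At least 1 UMI of 12 markers of B cells, myeloid cells, erythroid cells or platelets was found in 36 WT cells (1.71%) and 29 Lta-/- cells (1.33%), and at least 5 UMIs in 0 and 5 cells.

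Between genotypes, some genes of suppression and of early activation were higher in the Lta-/- cells, and most members of these lists were less than 1.5-fold apart. Of 15 measured suppressive molecules, 7 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.39 at the 100th percentile of the random lists. Over the members with at least 100 UMIs the median was 0.16 (interval -0.17 to 0.76), so no direction of the list was detectable there. Lag3, an inhibitory receptor (log2 1.43, interval 0.99 to 1.89), Gzmb, a cytotoxic protease (1.37), Penk, the enkephalin precursor (0.76), and Fgl2, a secreted suppressive protein (0.66), were among them. Il10, a suppressive cytokine, had 61 UMIs in 16 Lta-/- cells and 6 UMIs in 5 WT cells (log2 3.39, interval 2.18 to 4.89), so few cells carried it. Gzmb likewise came from 25 Lta-/- and 19 WT cells. Of 221 measured listed genes, 19 were at least 1.5-fold higher in Lta-/- and 6 lower. That is 11.3% of them apart, against 7.06% of all measured genes.

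Of 21 activation and immediate-early genes, which respond within minutes of receptor signalling, 4 were higher (Nr4a1, Egr1, Junb and Dusp4) and 0 lower, with a median of 0.32 at the 100th percentile. Junb stood at 326 CPM in Lta-/- and 209 CPM in WT. In effector-like, follicular-like and resting-like cells its log2 ratios were 0.68, 0.58 and 0.69. Nr4a1 (-0.07, interval -0.50 to 0.37) and Egr1 (0.08, interval -0.19 to 0.36) were not apart in follicular-like cells. Nr4a1 was higher in effector-like (1.35) and resting-like cells (1.07), and Egr1 was lower in the first (-0.69) and higher in the second (0.68). The intervals of Dusp4 held 0 in each of these classes. Of 8 heat shock and dissociation genes, 2 were lower and 0 higher, with a median of -0.24 at percentile 0.030. Its interval of -1.37 to 0.05 held 0, so no direction of the list was detectable. Hsph1, a chaperone, was 1.72-fold lower. Of 17 NF-kB pathway genes, 1 (Bcl3, 1.70-fold) was higher, and the median of 0.17 was at percentile 99.95. Of 10 cholesterol synthesis genes, 1 (Lss) was higher, with a median of 0.30 at the 100th percentile. Among the other listed genes, Socs3, an inhibitor of cytokine signalling, was 1.62-fold higher. Tnfrsf4, the OX40 receptor, was 1.54-fold higher, and Gpr183, an oxysterol receptor that guides migration, 1.54-fold higher. Gpr183 was higher in follicular-like (log2 0.55) and resting-like cells (0.65) but not in effector-like cells (-0.16, interval -0.48 to 0.16). Tnfrsf4 was not apart in resting-like cells (0.09, interval -0.15 to 0.33). Of 22 homing genes, 3 were higher and 2 lower. Cxcr6 was 2.13-fold higher, and Ccr2, a chemokine receptor for tissue entry, was 1.56-fold lower. This call was not kept within effector-like cells, where Ccr2 was 1.25-fold lower (log2 -0.32, interval -0.58 to -0.06) and which were the smaller share in Lta-/-. In follicular-like cells Ccr2 had 21 UMIs in 5 Lta-/- and 3 UMIs in 2 WT cells. Glycolysis, oxidative phosphorylation, T cell receptor signalling, T cell transcription factor and apoptosis genes had 0 members at least 1.5-fold apart. Of 11 Treg identity genes, 1 (Tnfrsf4) was higher and 0 lower, and of 82 ribosomal protein genes 1 was lower.

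H2-Q7, a nonclassical MHC class I gene (ENSMUSG00000060550, chromosome 17, 35439155 to 35443773), stood at 1114 CPM in Lta-/- and 423 CPM in WT (2.63-fold, log2 1.40, interval 1.34 to 1.45) and was the 1 of 12 listed MHC class I and antigen processing genes apart. Of unlisted MHC class I genes near Lta, H2-Q6 was higher (log2 1.11) and H2-M3 lower (-0.65), both named after their values were seen. H2-Q7 is near-identical to neighbouring H2-Q genes, so its count is uncertain. Genes at least 1.5-fold apart were more frequent within 10 Mb of Lta, at 7.69% of 208 genes, than in the rest of the genome, at 2.80%. Without H2 and numbered Gm genes these were 6.01% of 183 genes and 2.69%, with intervals that overlap. Among unlisted genes not used in the clustering, Glo1, a glyoxalase (ENSMUSG00000024026, chromosome 17, 30584936 to 30626871, 2.53-fold), Tec, a kinase (2.08-fold), Abca3 (1.79-fold), Dus2 (1.75-fold) and the T cell receptor segment Trbv2 (1.73-fold) were the highest in Lta-/-. Ly6k (3.29-fold), Cd86 (2.75-fold), E030030I06Rik (2.49-fold), 2610035D17Rik (2.17-fold) and Znrf3 (1.79-fold) were the lowest. Within effector-like, follicular-like and resting-like cells, Glo1 was higher in each (log2 1.01, 1.16 and 1.26). Tec was higher in resting-like cells (1.73) but not in follicular-like cells (-0.08), and its interval in effector-like cells held 0. Abca3 had an interval above 0 only in follicular-like cells (1.61), where Dus2 was not apart (0.20). All class intervals of Trbv2 and Znrf3 held 0, and those of Ly6k did not.

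**Figure D1:**
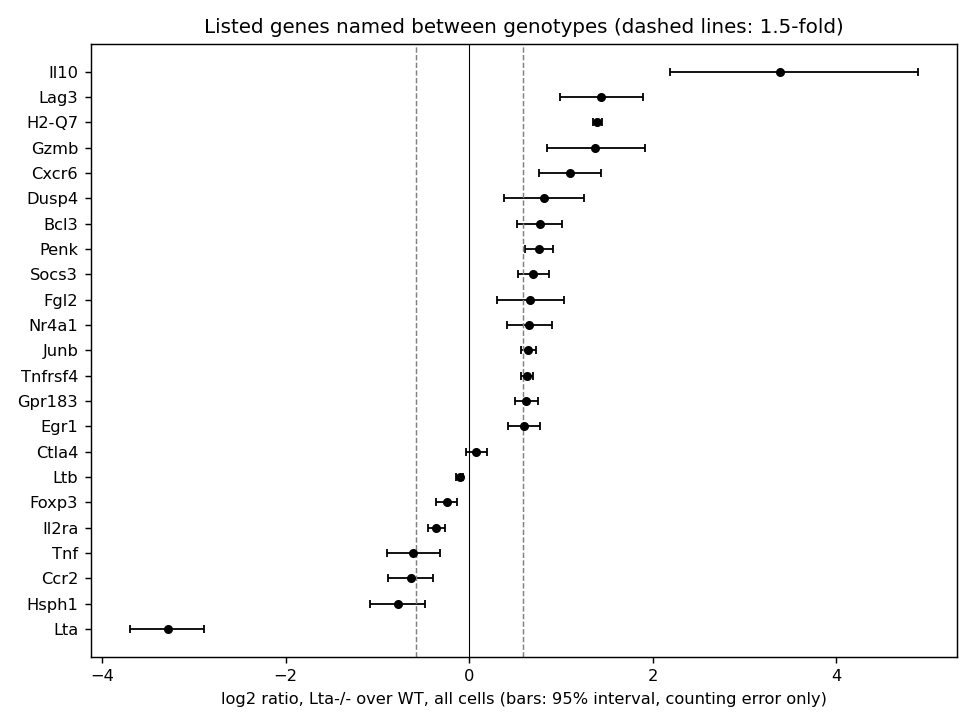
Log2 ratio of CPM, Lta-/- over WT, for the listed genes named between genotypes, over all cells of 1 mouse each. Points are ratios of summed UMIs, bars 95% intervals of counting error and dashed lines 1.5-fold; Lta lies lowest at -3.28 and Il10, from few cells, highest at 3.39.

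**Figure D2:**
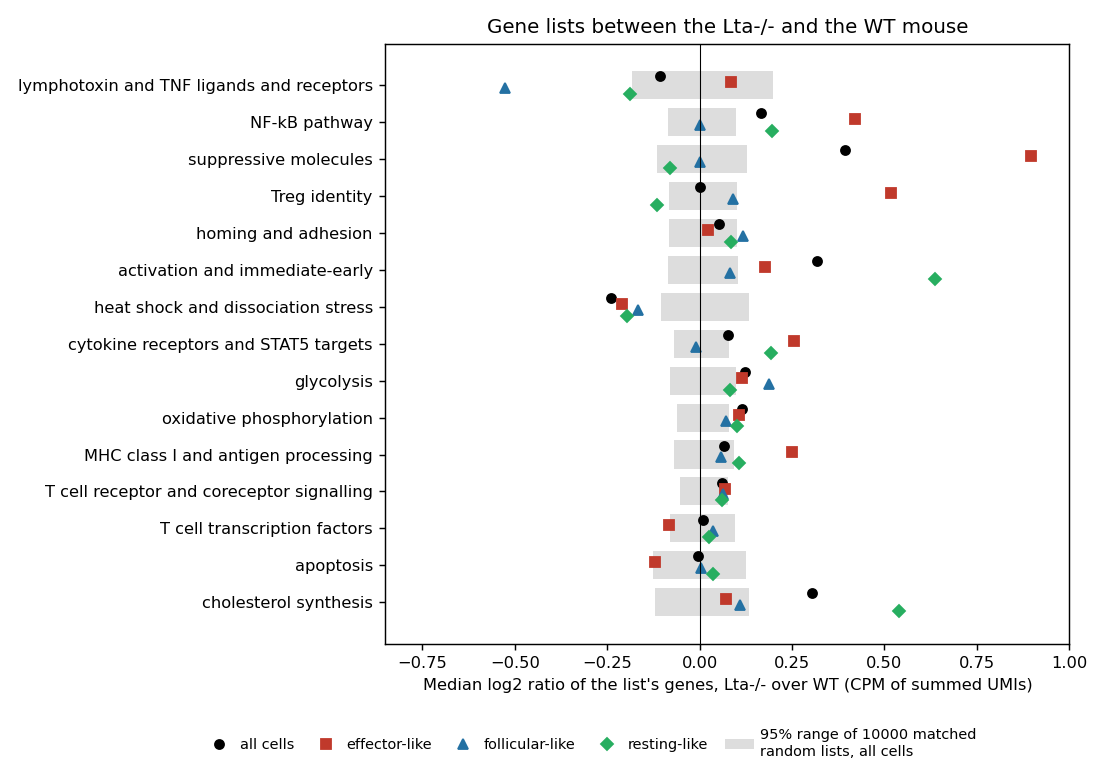
Median log2 ratio, Lta-/- over WT, of each gene list over all cells and within the 3 large named classes, with the 95% range of 10000 expression-matched random lists for all cells in grey. The suppressive list lies at 0.39 over all cells and at 0.90 in effector-like cells.

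**Figure D3:**
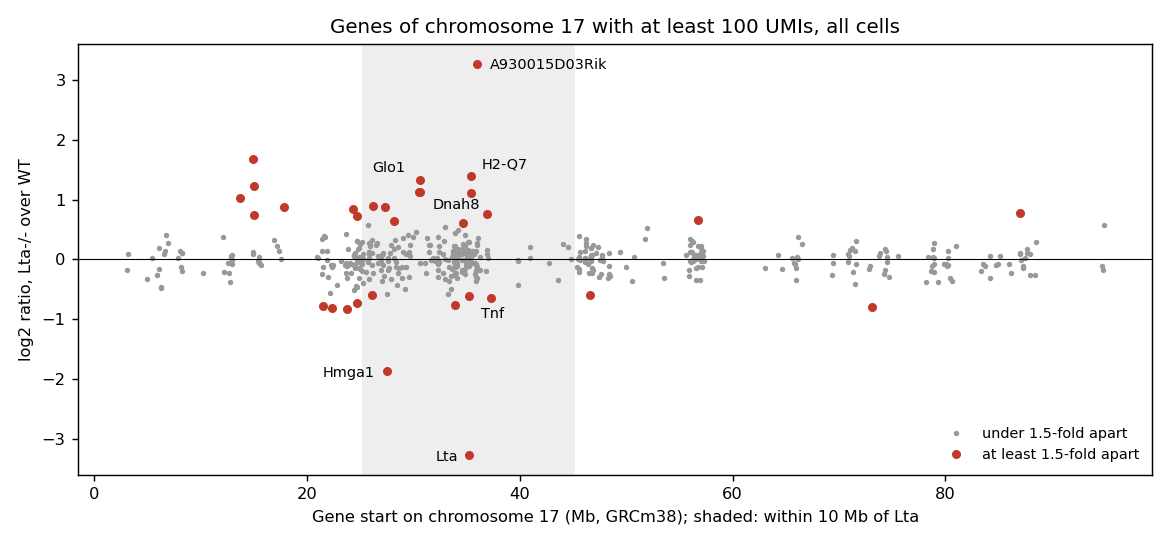
Log2 ratio of CPM, Lta-/- over WT, against gene start on chromosome 17 for genes with at least 100 UMIs over all cells. Each point is a gene, red marks genes at least 1.5-fold apart, and the grey band spans 10 Mb on each side of Lta, where 16 of 208 genes other than Lta were apart.

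Clustering gave 9 clusters. The 4 named classes were effector-like (624 cells), follicular-like (773), resting-like (904 in clusters 4 and 7) and interferon-like (56); 1929 cells stayed unnamed, of which 127 formed a shallow cluster with a median of 1262 UMIs. Effector-like cells were 14.6% of the Treg cells (interval 13.5 to 15.7). This share was 30.5% when the UMIs were split at random and clusters came from one part. No follicular-like class was named in that split. The follicular-like name rests on 5 markers that were higher in the cluster, and 2 of its 10 leading genes were such markers. Penk, Cd83, Cst7, Nrn1 and Tnfrsf9 led it. In the whole library 10 WT and 32 Lta-/- cells had UMIs of at least 3 of the 6 follicular markers. Most cells of the class are therefore not shown to be follicular one by one.

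Effector-like cells were a smaller share of the Lta-/- cells, at 11.8% (interval 10.5 to 13.2) against 17.4% in WT (interval 15.8 to 19.1). Of the genes used in the clustering, 574 were among 2743 genes at least 1.5-fold apart between genotypes, over all cells or within a large named class. The share was therefore also taken from a clustering without those genes. It was then 10.3% in Lta-/- and 14.6% in WT. With clusters from a random part of the UMIs the difference, Lta-/- minus WT, was -1.53 percentage points (interval -4.32 to 1.26) and was not detectable. The summed UMIs of the 10 effector markers went the other way, at 1945 CPM in Lta-/- and 1725 CPM in WT (log2 0.17, interval 0.14 to 0.20), while cells with at least 3 of these markers were 36.8% and 39.1%. The summed KLRG1/ST2 effector markers were 240 and 196 CPM (log2 0.29, interval 0.20 to 0.38), with at least 3 of them in 4.35% and 3.42% of cells. Follicular-like cells were 19.5% in Lta-/- and 16.5% in WT, and 13.9% and 13.0% without those genes, a difference not detectable there. Resting-like cells were 24.1% and 18.0%, but 45.4% and 45.9% without those genes, so no direction is given for them. Interferon-like cells were 0.825% of Lta-/- and 1.81% of WT cells, and 0.687% and 1.81% without those genes.

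**Figure D4:**
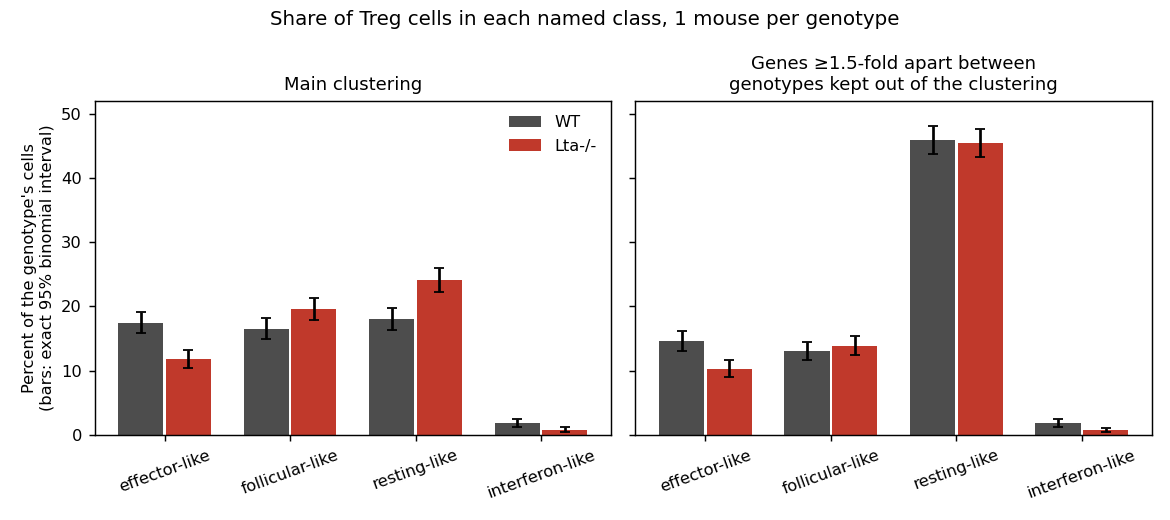
Percent of each genotype's cells in the 4 named classes, in the main clustering and without genes at least 1.5-fold apart between genotypes. Bars are shares of 2104 WT or 2182 Lta-/- cells with exact 95% binomial intervals. Effector-like cells are the lower share in Lta-/- in both panels. The resting-like difference is seen in the panel of the main clustering and not in the other panel.

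Within effector-like cells, 10 of 14 suppressive molecules were at least 1.5-fold higher in the Lta-/- mouse and 0 lower, with a median log2 ratio of 0.90 at the 100th percentile. Gzmb (log2 2.15, from 17 Lta-/- and 12 WT cells), Cxcr6 (1.88), H2-Q7 (1.70), Socs2 (1.68), Penk (1.61, from 14 cells in each mouse), Fgl2 (2.83-fold) and Tnfrsf4 (1.24) were among the 8 named genes, and Fos, an immediate-early factor, was lower (-2.52, from 10 Lta-/- and 25 WT cells). Of 14 activation and immediate-early genes, 5 were higher (Nr4a1, Jun, Junb, Dusp1 and Dusp5) and 2 lower (Egr1 and Fos), with a median of 0.18 (interval -0.28 to 0.69). Of 11 Treg identity genes, 5 were higher, Il2ra and Tnfrsf18 among them, with a median of 0.52 (interval -0.11 to 1.24), so no direction of the list was detectable. Of 17 NF-kB genes 5 were higher, with a median of 0.42. Il10 had 52 UMIs in 9 Lta-/- cells and 2 UMIs in 2 WT cells. The suppressive median was 0.18 under a stricter filter on cells (interval -0.19 to 0.80), where no direction was detectable. It was 0.35 at a Leiden resolution of 1.5, 0.39 without the genes apart between genotypes in the clustering and 0.51 with split UMIs. At a resolution of 1.5 a separate KLRG1/ST2-like class of 162 cells was named, at 4.58% of Lta-/- and 2.95% of WT cells.

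In follicular-like cells, 3 of 6 lymphotoxin and TNF family genes were lower in the Lta-/- mouse and 0 higher, with a median of -0.53 at percentile 0.010, Lta (-3.08), the deleted gene, and Tnf (-0.89) among them. Without Lta, 2 of 5 were lower and 0 higher, with a median of -0.33 (interval -0.89 to -0.15) at percentile 1.15. Of 12 suppressive molecules 1, Lag3 (log2 1.33), was higher, with a median of 0.00. H2-Q7 (1.52) and Socs3 (0.79) were higher. Nr4a3 (-0.97) and Socs2 (-0.77) were lower and Idi1 (0.67), a cholesterol synthesis enzyme, higher. Listed genes were apart less often in this class than all measured genes, at 7.43% against 9.58%. In resting-like cells, 8 of 14 activation and immediate-early genes were higher and 0 lower (median 0.64, 100th percentile), and 4 of 9 cholesterol synthesis genes were higher (median 0.54, percentile 99.98). The class joined clusters 4 and 7, and cluster 7 held 187 of the 525 Lta-/- and 99 of the 379 WT cells. In cluster 4 alone, 7 of 13 activation genes were higher (median 0.65), and in cluster 7 alone 4 of 9 (median 0.57). The cholesterol medians were 0.55 (interval -0.12 to 0.88) and 0.75 (interval 0.39 to 1.31, 4 genes). In the clustering without the genes apart between genotypes, 38.9% of the resting-like cells were resting-like in the main one, and the medians were 0.42 and 0.33. With split UMIs the activation median was 0.41 (interval -0.13 to 0.66), and at a Leiden resolution of 1.5 the cholesterol median was 0.26 (interval -0.02 to 0.45), so neither direction was detectable there. In the main resting-like class, H2-Q7 (1.28), Lgals1 (1.10), Socs3 (1.08), Dusp5 (1.00), Gpr83 (0.88) and Zfp36 (0.88) were higher, and Cd200 (-1.03) and Capg (-0.96) lower.

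Effector-like and resting-like cells were compared over both mice. Effector-like cells carried more transcripts for suppression, tissue homing and glycolysis, and fewer of Bcl2, Bcl2l11, Foxp1 and Gpr83. Of 213 listed genes, 82 were at least 1.5-fold higher and 16 lower in effector-like cells. That is 46.0% of them apart, against 29.4% of all measured genes. The median of all genes was 0.20 on the log2 scale, and without ribosomal protein and mitochondrial genes in the CPM the counts were 54 and 31. Of 68 listed genes at least 1.5-fold higher in effector-like cells of the WT mouse, 61 had the same direction in the Lta-/- mouse and 54 were 1.5-fold apart there. Of 75 chosen in the Lta-/- mouse, 72 and 54 were so in the WT mouse. For lower genes these were 15 and 12 of 18, and 18 and 12 of 21. The classes came from a clustering of both mice, so this is not an independent check.

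Of 14 suppressive molecules, 12 were higher and 0 lower (median 3.01, 100th percentile). Within the WT mouse 8 of 11 were higher and 1, Cd200, lower, with a median of 1.06 (interval -0.33 to 4.96), so no direction of the list was detectable there. Within the Lta-/- mouse 11 of 13 were higher and 0 lower (median 2.69, interval 1.12 to 6.00). Lgals1, a galectin, stood at 1085 CPM in effector-like and 165 CPM in resting-like cells (log2 2.72, interval 2.60 to 2.85). Fgl2 was 67.8 and 0.781 CPM (3 UMIs in resting-like cells, log2 6.44, interval 4.87 to 8.73), Gzmb 43.9 and 0.521 CPM (2 UMIs, log2 6.40, interval 4.51 to 9.46) and Penk 63.6 and 2.60 CPM. Ctla4 was 2.09-fold higher, and Il10 at least 24.3-fold higher, from 11 cells with 54 UMIs against 0. Of these Il10 UMIs, 52 came from the Lta-/- mouse, and without it 2 UMIs remained, too few for a difference. Within WT and within Lta-/- cells the log2 ratios were 3.33 and 2.45 for Lgals1, 4.96 and 7.40 for Gzmb (1 UMI in resting-like cells of each), and 3.89 and 5.20 for Penk. Of 21 homing genes, 13 were higher and 2 lower (median 1.12, 100th percentile). The homing medians were 1.08 within WT (interval 0.06 to 4.06) and 1.21 within Lta-/- cells (interval -0.17 to 3.24), where no direction of the list was detectable. Ccr2 was at least 234-fold higher, with 520 UMIs against 0, and at least 115-fold within WT and 112-fold within Lta-/- cells. Cxcr6 (log2 8.56, interval 6.07 to 13.86, 1 UMI in resting-like cells), Ccr4 (log2 6.77, interval 4.90 to 9.83, 2 UMIs) and Ccr6 (3.61) were higher. Within WT cells, with 0 UMIs in resting-like cells, Cxcr6 was at least 26.7-fold and Ccr4 at least 28.8-fold higher, and within Lta-/- cells their log2 ratios were 8.49 and 6.14. Also higher were the adhesion molecules Cd44 (2.36), Itgal (1.34) and Itgav (1.31), while Ccr9 (-2.33), a gut-homing receptor, was lower.

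Of 14 glycolysis genes, 11 were higher and 0 lower (median 0.72, percentile 99.98), Tpi1 (1.54) and Pfkp (1.39) among them. Of 13 apoptosis genes, 7 were higher and 2 lower, with Bcl2l11, which promotes cell death, lower (-2.40). Bcl2, which opposes it, was also lower (-2.28). Of 15 T cell transcription factors, 3 were higher and 3 lower: Rora (2.82) and Runx3 (1.84) were higher and Foxp1 (-1.54), a quiescence factor, lower. Capg (2.54), Nrp1 (1.41), Tnfrsf1b (2.14) and Il10ra (2.05) were higher, and Gpr83 (-3.17) and Myc (-1.86) lower. Within WT and within Lta-/- cells the log2 ratios were 1.95 and 3.23 for Capg and 1.38 and 2.83 for Tnfrsf1b. Foxp3 was 127 CPM in both classes (log2 -0.00, interval -0.20 to 0.20), and Il2ra was 116 and 140 CPM. Within WT cells the log2 ratios were -0.30 for Foxp3 and -0.70 for Il2ra, and within Lta-/- cells 0.31 and 0.19, a difference that was not tested. Of 81 ribosomal protein genes, 24 were lower and 1 higher. Lta was 15.8 and 8.85 CPM, a direction that turned in 5 of the clusterings tried, as with 40 principal components (log2 -0.73). The log2 ratio of Lta was 0.54 within WT cells (interval -0.20 to 1.29) and 0.83 within Lta-/- cells (interval -1.07 to 2.74, 6 UMIs in each class), so no difference was detectable within either mouse. Ltb was 1311 and 1071 CPM and Tnf 17.2 and 12.2 CPM, with an interval of the log2 ratio for Tnf of -0.12 to 1.10. Ltb lay at -0.031 under a stricter filter on cells and Tnf at -0.23 with 40 principal components, so neither is given a direction. The log2 ratio of Tnf was 0.93 within WT (interval 0.06 to 1.85) and -0.02 within Lta-/- cells. Among unlisted genes, Acot7 (2.84), Sdcbp2 (2.71), Matk (2.67), Gna15 (5.67-fold) and Unc119 (2.41) were the highest, and Ms4a4c (-2.78), Igf2r (-2.26), Nsg2 (-2.21), Treml2 (-1.97) and Rras2 (-1.64) the lowest. Their order differed between the mice: within WT and within Lta-/- cells Gna15 was 19.5-fold and 3.79-fold higher, and the log2 ratios were -2.36 and -3.81 for Ms4a4c and -0.99 and -2.37 for Rras2.

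Follicular-like cells, set against all remaining Treg, had higher transcripts of some lymphotoxin and TNF family, activation and NF-kB genes, and lower transcripts of most cholesterol synthesis genes. Of 221 listed genes, 61 were at least 1.5-fold higher and 41 lower. That is 46.2% of them apart, against 25.9% of all measured genes. Of 21 activation genes, 11 were higher and 2 lower (median 0.71, 100th percentile), with Nr4a3 (2.68), Irf4 (2.35) and Egr3 (2.33) leading. Of 8 heat shock and dissociation genes, 4 were higher and 0 lower (median 0.36, interval -0.07 to 1.09, percentile 97.62), and whether handling stress added to the activation genes was not tested. Penk (319 against 20.2 CPM, log2 3.98) and Lag3 (2.64) were higher, and Ccr9 (-2.91) and Ccr2 (-2.37) lower. Gzmb had 2 UMIs in follicular-like cells (log2 -4.08, interval -7.13 to -2.20). Within WT and within Lta-/- cells the log2 ratios were 3.44 and 1.90 for Nr4a3, -3.64 and -2.57 for Ccr9, -4.46 and -1.34 for Ccr2, and -2.99 and -4.84 for Gzmb. The activation medians were 0.52 (interval -0.01 to 2.35) and 0.60 (interval -0.09 to 1.90), so no direction of that list was detectable within either mouse. Of 17 NF-kB genes 7 were higher and 0 lower (median 0.52, percentile 99.98), of 7 lymphotoxin and TNF family genes 4 were higher (median 1.17, interval -0.57 to 2.12, which holds 0), and of 10 cholesterol synthesis genes 8 were lower and 0 higher (median -0.78, percentile 0).

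Interferon-like cells, 56 in number with 269533 UMIs, had higher antigen presentation transcripts. The class held 367 cells when cells with a UMI of another cell type were left out, so its extent depends on the clustering. Of 12 MHC class I and antigen processing genes, 7 were higher and 0 lower (median 0.80, 100th percentile), Tap1, Psmb8, Psmb9 and Nlrc5 among them. The 8 listed genes with the largest ratios were all lower and rested on 0 to 4 UMIs in these cells. Penk, with 0, was at least 6.86-fold lower, and Nr4a1, with 1, had a log2 ratio of -2.98 (interval -8.29 to -0.50). Tpi1 had 4 (log2 -1.68, interval -3.56 to -0.32). The intervals of Fos, Myb, Fgl2, Egr2 and Ccr4, with 1 UMI each, held 0, so no difference was detectable at this depth. Within single mice, Nr4a1 and Tpi1 were at least 1.5-fold apart in 1 mouse each, with intervals that held 0, and Penk was at least 3.58-fold lower in WT and 2.60-fold in Lta-/- cells. The antigen presentation medians were 0.69 within WT and 0.99 within Lta-/- cells.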

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

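All tests in this part were chosen after the results were seen, except the Glo1 test of hashtag calls, the test of class composition and the alternatives with a stricter filter on cells and a Leiden resolution of 1.5.

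Egr1 and Fos, both immediate-early genes, had opposite directions between genotypes in 2 classes. Fos was lower in Lta-/- effector-like cells (log2 -2.52, interval -3.53 to -1.65) and higher in Lta-/- resting-like cells (1.66, interval 0.79 to 2.63). Egr1 was lower in the first (-0.69, interval -1.36 to -0.05) and higher in the second (0.68, interval 0.14 to 1.24). The search asked for at least 1.5-fold in opposite directions. With at least 100 UMIs in each class, the minimum tried first, it found 0 of 142 listed genes; with at least 30, tried after that, it found these 2 of 185. The difference between classes was not tested. Of 14 such genes in effector-like cells, 5 were higher and these 2 lower. In WT effector-like cells, 77 of the 97 Fos UMIs came from 5 cells.

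Genes near Lta on chromosome 17 were apart between genotypes more often than elsewhere. Within 10 Mb of Lta, Lta itself left out, 7.69% of 208 genes were at least 1.5-fold apart (interval 4.46 to 12.2) against 2.80% of 8581 in the rest of the genome (interval 2.46 to 3.17). Reads shared between paralogs cannot be told apart from a regional excess: without H2 and numbered Gm genes the shares were 6.01% of 183 genes (interval 3.04 to 10.5) and 2.69% of 8440 (interval 2.35 to 3.06), and the intervals overlap. The 11 genes apart that remain include A930015D03Rik (log2 3.28, 132 UMIs in Lta-/- and 14 in WT, chromosome 17, 35994453 to 36038435), Glo1 and Hmga1 (-1.87), and Glo1 and Dnah8 overlap and are not independent. Of 32 pairs of such a gene and a large class, 96.9% had the direction of all cells. The genes were chosen over all cells, which include these classes, so this is partly built in. It asks only for direction, and the pairs are not independent. Class composition is therefore not excluded for the excess. It does not account for Glo1 (log2 1.01, 1.16 and 1.26 in effector-like, follicular-like and resting-like cells) or for the H2-Q7 count (1.70, 1.52 and 1.28). A chromosomal region carried along with the targeted allele is a candidate explanation that the excess is consistent with, although the rest of chromosome 17 also had 5.38% apart, and an effect of losing Lta on its neighbours, Tnf included, was not tested.

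Lta-/- cells kept 58 Lta UMIs. Free RNA from WT cells would give a like level in every class. Lta was 1.97 times higher in follicular-like than in other Lta-/- cells (interval 1.09 to 3.47), beside 1.55 in WT cells. This rests on 20 against 38 UMIs and on an interval that treats them as independent draws. At most it argues against free RNA as the only source. Free RNA would also reach resting-like cells. There Ccr2, Cxcr6, Ccr4, Penk, Fgl2 and Gzmb, higher in effector-like cells, stood at 0% to 6.67% of their CPM over all cells. Lta in Lta-/- cells stood at 18.5% of its CPM over all cells. If free RNA held Lta in like proportion to these genes, the values argue against it as the main source. They rest on few UMIs in resting-like cells, and a part from free RNA is not excluded. WT cells with a wrong hashtag call would carry the WT level of Glo1, but Glo1 in Lta-/- cells with an Lta UMI was 1.03 times that in Lta-/- cells without (interval 0.764 to 1.35), where WT cells stood at 0.396. Transcripts still made from the targeted allele may remain, which was not tested, as the labels do not give the removed part.

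Suppressive genes were higher in Lta-/- effector-like cells (median log2 0.90). Without the 5 cells with most UMIs of each gene per genotype the median was 0.75. The minimum of 30 UMIs was applied again to the reduced sums, so genes found in few cells could leave the list. The removal raised some log2 ratios, as Gzmb from 2.15 to 2.59, and lowered others, as Ctla4 from 0.74 to 0.52. Whether a few cells with many UMIs carry the difference is therefore not decided. More WT cells near the class boundary cannot be told apart from a difference in level: listed genes lower in effector-like cells had a median of 0.0106 between genotypes (interval -0.38 to 0.56). The 78 listed genes higher in effector-like cells, suppressive ones included, had a median of 0.25 (interval 0.13 to 0.39), which goes with that explanation. They were chosen over both mice pooled, which favours genes high in Lta-/- effector-like cells, so a positive median is partly built in. No median was taken without the suppressive genes. The suppressive median was 0.18 under a stricter filter on cells (interval -0.19 to 0.80). A different mix of effector subsets also stays open: at a Leiden resolution of 1.5 a KLRG1/ST2-like class held 4.58% of Lta-/- and 2.95% of WT cells, and the median in the remaining effector-like cells was 0.35. A difference between 2 mice other than genotype also stays open, with 1 mouse per genotype.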

How the results depend on the processing

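No paired analysis of genotype was possible because 1 mouse was sampled per genotype. Class differences were also taken within each mouse, and no test over both mice was made. The alternatives on Scrublet scores, other cell types, shallow cells, seeds 2 and 3, genotype genes in the clustering, the scaling of genotype ratios, the resting-like clusters taken alone, and for genotype the cells with most UMIs, thinned shares, class composition and CPM without ribosomal protein and mitochondrial genes, and for genotype and other classes the count minimums, were chosen after seeing the data. Over 26 settings, 214 of 242 values that answer a comparison stayed within their interval or within 1.5 times the count. Of the others, 26 moved out and 2 reversed direction. Of 415 values of the 32 genes named between genotypes, 413 lay on the same side of 0, and of 667 values of the 42 named between effector-like and resting-like cells, 653. The log2 ratio of Lta between genotypes lay between -3.46 and -3.03. Keeping the cells marked by Scrublet repeated the main values, since 0 were marked. Leaving out the shallow cluster kept the main classes, so ratios between effector-like and resting-like cells could not change. Both settings add to the counts of unchanged values above. With split UMIs no follicular-like class was named, so it has no value there. Depth limits the shares of cells with a UMI.

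With every deposited barcode, effector-like cells were 12.8%, cells with a Foxp3 UMI 36.4%, the resting-like difference (Lta-/- minus WT, in percentage points) 0.229, the median log2 ratio of activation genes between genotypes in resting-like cells 0.32 and the log2 ratio of Lta between effector-like and resting-like cells -0.81. With the stricter filter, which left 3965 cells, effector-like cells were 11.8%, the resting-like difference 13.6, the suppressive median in effector-like cells 0.18 and the Ltb ratio -0.031. Without the highest 5% of Scrublet scores, effector-like cells were 12.5%, listed genes lower in them 30 and the Lta ratio -0.92. At a Leiden resolution of 0.5 these were 12.3%, 29 and -0.88 and the resting-like difference -4.16. At 1.5, effector-like cells were 12.6%, the follicular-like difference 0.264 and the resting-like difference 2.95. With 40 principal components, effector-like cells were 12.3%, listed genes lower 27 and the Lta ratio -0.73. With gene-group genes in the clustering, effector-like cells were 16.3% and the resting-like difference 2.37. Without genes apart between genotypes, effector-like cells were 12.4%, the resting-like difference -0.448, the Lta ratio -0.17 and the Ltb ratio -0.00138. With split UMIs, effector-like cells were 30.5%, their difference -1.53 and the Il2ra ratio 0.13. Seed 3 gave a follicular-like difference of 0.145. Thinning to 2000 UMIs gave shares of 20.6% for Foxp3 and 4.91% for Lta. CPM without ribosomal protein and mitochondrial genes gave 54 listed genes higher and 31 lower. Thinning lowers shares by its construction, and for the others the cause was not tested.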

Other observations

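The first paragraph describes values outside the comparisons of the report, with clusters chosen after the data were seen. Of the cholesterol synthesis genes, 2 of 10 were at least 1.5-fold higher in Lta-/- cells in cluster 1, 4 of 9 in cluster 5 and 3 of 8 in cluster 6, the 3 large unnamed clusters, and 0 were lower. Their median log2 ratios were 0.37, 0.53 and 0.51 (interval in cluster 6 -0.13 to 0.74). In effector-like and follicular-like cells it was 0.07 and 0.11. Activation and immediate-early genes had medians of 0.51, 0.43 and 0.36 in clusters 1, 5 and 6 (interval in cluster 5 -0.16 to 0.68), with 7 of 16, 4 of 14 and 4 of 10 higher and 0, 1 and 0 lower. Cluster 1, led by Treml2 and Zfp608, held 483 of 2104 WT and 323 of 2182 Lta-/- cells, and cluster 5, led by G0s2 and Ldlr, 225 and 362.

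Proliferation markers summed to 147 CPM in WT and 79.9 CPM in Lta-/- cells. Cells with UMIs of at least 3 of the 11 markers numbered 19 in WT and 12 in Lta-/-, and Stmn1 alone was found in 144 WT and 197 Lta-/- cells. Follicular markers summed to 588 UMIs in WT and 1105 UMIs in Lta-/- cells. B cell markers summed to 312 CPM in WT and 472 CPM in Lta-/- cells. Ighm gave 2419 of these 3059 UMIs in WT and 2967 of 4496 in Lta-/-, and was found in 51.2% and 58.6% of cells. Of the 12 markers of other cells, a set without Ighm, 313 of the 339 UMIs in Lta-/- came from 5 cells. Those 5 cells therefore do not account for the B cell marker difference, whose source was not tested.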
